A study of Bacillus subtilis subsp. subtilis str. 168 with 12 samples.

How the data were processed

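RNA was measured in 12 samples of Bacillus subtilis, in 6 groups of 2: the pGpp strain and the (p)ppGpp strain, each at 0, 10 and 20 min. Per the labels' protocols, total RNA was extracted with Trizol and chloroform, treated with DNase and made into libraries with a stranded total RNA ligation kit with rRNA depletion. The values used are counts of fragments per gene, which the authors deposited as 1 table. Per the file headers, paired fragments were counted with featureCounts 2.0.3 over coding sequence and exon features grouped by gene name, with no strand option, no counting of multi-mapping fragments and no counting of fragments that overlap more than 1 gene. Bowtie2 2.5.1 is named per the submitters' processing notes, and its settings are not given in the sources used here. Since strand was not used in counting, fragments from a gene and from an antisense or overlapping gene cannot be told apart, and fragments in an overlap of 2 genes are not counted for either. Of the 192 named genes, 58 overlap another gene in the table's annotation, and their values are uncertain in that part. Copies of near-identical genes, such as those for rRNA, lose fragments that map to more than 1 of them.

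Groups came from the sample labels. The series design text says that 2 biological replicate cultures of each strain were sampled repeatedly, so within a strain the replicate number pairs samples by culture, and across strains it is only a number. Deviations from the group means of the same culture correlated across genes at 0.0811 to 0.388 between its times. Between libraries of the 2 strains that share a number the range was 0.135 to 0.398, so the number carries about as much across strains. The main test has no culture term, and the culture block is an alternative. The 2 libraries of each group differed by far more than sampling noise, with a chi-square per degree of freedom of 35.6 to 288.

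All 4441 gene symbols of the table were matched to a reference gene table of assembly ASM904v1, which was used for old and new names. Coordinates are those of the authors' table, counted from 1 on the chromosome. The 30 rRNA features, at most 5.75% of a library, were left out of library sizes and tests. After edgeR's filterByExpr on the 6 groups, 4352 genes were tested with the quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM factors. There was 1 fit over all 12 samples with 6 group means and 6 residual degrees of freedom, and a Benjamini-Hochberg adjusted p under 0.05 (two-sided) as the threshold. The common biological coefficient of variation was 0.134 and the prior degrees of freedom were 4.11. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels in CPM use TMM-scaled library sizes, and log values use a prior count of 2. An adjusted p that DESeq2 (1.42.0) gave as NA stayed NA.

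Before the data were examined, 42 gene lists with 824 genes, the tests, most alternatives and the rule for named genes were fixed. Of the list genes 820 were found in the table and 4 were not. The 41 lists with at least 4 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), which asks whether a list moved against all other genes. It used Benjamini-Hochberg adjustment over the lists of a comparison. The lists described in the text were picked among those after the values were seen. The rule named the genes of the constructs and the inducer, the 8 largest rises and falls in each comparison with 0 min and the 5 largest each way in each difference and between the strains at 0 min. Such genes needed an adjusted p under 0.05, an average log2 CPM of at least 5 and the same direction in both cultures (in all 4 pairings of cultures for a difference), with at most 2 genes that share their first 3 letters. It also named the first gene of each described list and the up to 3 members with the smallest adjusted p. Genes outside this rule were chosen after their values were seen, because a count of 5 or fewer included them or because they were singled out: purT, rplI, pbpH, metK, prfB, metS, thrZ, trpS, yocK, fecC, asnS, sinR, bslA, engB, spoIIE, spo0B, kinC, ppsD, ppsE, albA, pgi and holB, epsI in the pGpp strain, csbX in the difference at 20 min, pstS at 20 min, and pstS, pstC and pstBB at 0 min.

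The tests were checked on simulated counts with known changed genes, drawn from the mean levels of the 0 min libraries and the sizes of all libraries. A log2 change of 1 was recovered for 83.6% to 91.0% of 67 changed genes in the 4 comparisons with 0 min. In the differences at 10 and 20 min it was 64.2% and 50.7% of 67. A log2 change of 0.5 was recovered for 8.96% to 22.4%, 2.99% and 4.48%. False calls were 1.79% to 6.48% of the calls. Small changes are therefore often missed, above all in the differences between strains. Alternatives were RLE factors, library totals alone, no low-count filter, rRNA kept, the culture block, the number as a block between strains at 0 min, fits of 1 strain, DESeq2 and a change of at least 2-fold. Further ones were camera with an estimated correlation, the directional test fry, and each library left out. Chosen after seeing the data were thinning each library to 18.2 M fragments and the number block for the differences and levels between strains.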

Results

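Transcripts of Bacillus subtilis were counted in 12 libraries from 2 engineered strains grown in S7 minimal medium. The alarmones ppGpp and pppGpp, together (p)ppGpp, and their relative pGpp are guanine nucleotides that bacteria make under stress. Both strains lacked the chromosomal alarmone synthetase genes sasA, sasB and rel and carried a copy of sasA at the amyE locus under the xylose promoter. The pGpp strain kept nahA, whose product hydrolyses (p)ppGpp to pGpp. In the (p)ppGpp strain nahA was deleted as well. Each strain was sampled before induction (0 min) and 10 and 20 min after it, from 2 replicate cultures followed over time. Library totals ran from 18.7 to 54.5 M fragments with a median of 30.8 M. The comparisons ask how the transcriptome changed after induction and how far the 2 strains differed. No uninduced or sasA-free culture was followed, so alarmone, xylose and time cannot be separated. Log2 fold changes are given ± their standard error, with n = 2 libraries per group. Adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Levels are in CPM (mean ± SD).

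The genes of the constructs were examined first. The sasA transcript, listed as relQ (positions 3949952 to 3950584 on the minus strand), rose from 26.5 ± 11.1 CPM at 0 min to 1299 ± 128 at 10 min and 1399.5 ± 63.6 at 20 min in the pGpp strain, and from 21.9 ± 4.59 to 1107 ± 101 and 967 ± 42.4 in the (p)ppGpp strain. Its log2 fold change was 5.62 ± 0.29 and 5.73 ± 0.29 in the pGpp strain and 5.66 ± 0.29 and 5.46 ± 0.29 in the (p)ppGpp strain. The deleted nahA, listed as yvcI (positions 3572413 to 3572889), was at 52.2 ± 3.53, 42.8 ± 16.4 and 37.1 ± 1.07 CPM in the pGpp strain at the 3 times and at 0.294 ± 0.0206, 0.269 ± 0.155 and 0.167 ± 0.0727 CPM in the (p)ppGpp strain. No fragment fell on sasB (relP, positions 1237006 to 1237641) in any of the 12 libraries, where 3 counts would be 0.0554 to 0.164 CPM. The deleted rel (rsh, positions 2820529 to 2822733) lay between 1.42 ± 0.120 and 4.85 ± 0.934 CPM over the 6 groups. In every library nahA was present or absent as the label of its strain says. At amyE (positions 327618 to 329597), the integration site, counts rose from 48.6 ± 2.27 to 563 ± 4.81 CPM in the pGpp strain and from 46.6 ± 4.62 to 394 ± 5.62 CPM in the (p)ppGpp strain by 20 min. The xylose isomerase gene xylA (positions 1891908 to 1893245), a native xylose-induced gene, went from 8.75 ± 1.62 to 1409.5 ± 235 CPM and from 7.54 ± 0.684 to 697 ± 29.7 CPM, and the xylulose kinase gene xylB (positions 1893396 to 1894895) had log2 fold changes of 5.41 ± 0.14 and 5.09 ± 0.14 at 20 min.

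**Figure D1:**
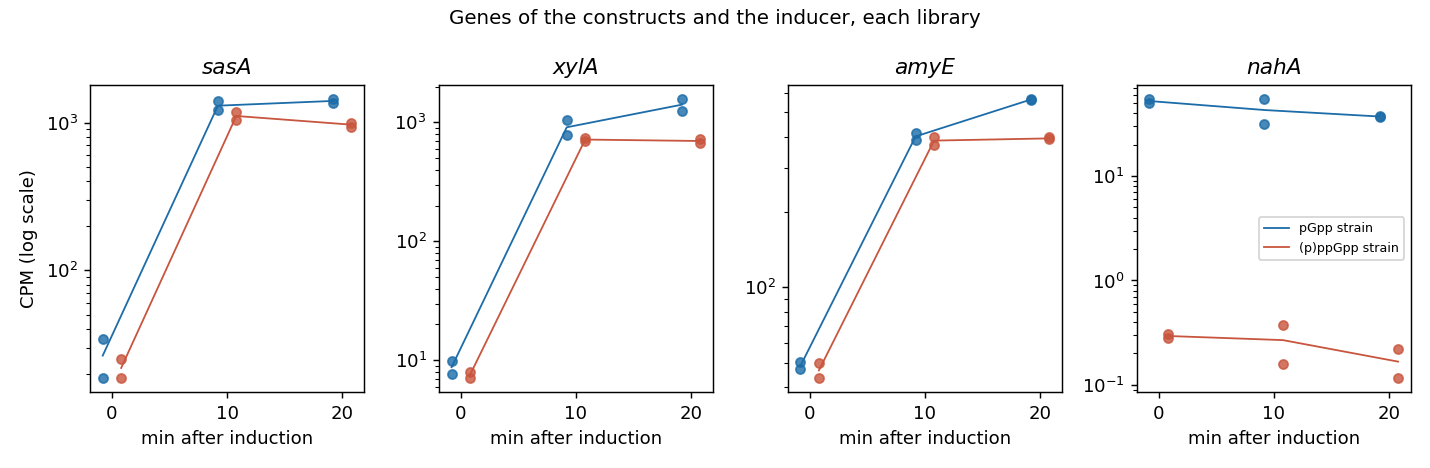
CPM (log axis) of sasA, xylA, amyE and nahA against minutes after induction, 1 point per library, with lines joining the means of the 2 libraries of each strain. The nahA points of the (p)ppGpp strain lie at 0.294 CPM or below on average, against 37.1 to 52.2 CPM in the pGpp strain.

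At 10 min in the pGpp strain, purine and pyrimidine synthesis genes fell and amino acid acquisition genes rose. The rule for named genes admits at most 2 that share their first 3 letters, so the genes given for each direction are not an order of all genes. Among the falls it named were purK and purE (-5.20 ± 0.20 and -4.99 ± 0.14), which encode steps of inosine monophosphate synthesis, the pyr operon regulator pyrR (-4.43 ± 0.13) and the hypoxanthine and guanine permease gene pbuG (-4.08 ± 0.32). The annotated short RNAs pyaB (-5.01 ± 0.23) and gswD (-4.81 ± 0.22) and the genes yrrM (-4.03 ± 0.16) and yrrN (-3.79 ± 0.14) were named as well. Rises named beside the xylose genes and sasA were yhzC (5.85 ± 0.46), yhxC (5.48 ± 0.14), the bacilysin synthesis gene bacA (5.45 ± 0.30), samT (5.36 ± 0.15), formerly yitJ, and the oligopeptide transporter gene appD (5.11 ± 0.22). The (p)ppGpp strain had purE at -4.27 ± 0.13, purK at -4.16 ± 0.19, pyaB at -4.57 ± 0.22, gswD at -4.14 ± 0.21, pyrR at -3.96 ± 0.12, pbuG at -3.01 ± 0.30, yrrM at -2.95 ± 0.15 and the GMP reductase gene guaC at -3.97 ± 0.17. Its rises named beside the xylose genes and sasA were samT (4.67 ± 0.14), appD (4.31 ± 0.21), bacA (4.29 ± 0.29), the oligopeptide transporter gene appF (4.22 ± 0.28) and the methylthioribose kinase gene mtnK (4.21 ± 0.17). Every gene in these sentences had an adjusted p of 1.8e-05 or less in edgeR, and changed the same way in both cultures.

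Of the 14 genes of de novo purine synthesis, 13 fell and 1 rose in each strain at 10 min, with the same numbers adjusted over the list alone. The median was -3.70 in the pGpp strain (camera adjusted p = 1.9e-10, and 0.218 with an estimated correlation). Purine genes of the (p)ppGpp strain had a median of -2.85 (camera adjusted p = 5.2e-13, and 0.219 with an estimated correlation). The exception was purT, a formate-dependent transformylase gene, at 1.30 ± 0.13 and 1.14 ± 0.13. In the pGpp strain purC stood at -4.94 ± 0.26, and in the (p)ppGpp strain purB at -3.87 ± 0.25. All 13 pyrimidine synthesis genes fell in both strains, adjusted over the list alone too, among them pyrB (-2.98 ± 0.12 and -2.93 ± 0.12) and pyrC (-3.00 ± 0.14 and -2.86 ± 0.13). Their medians were -2.36 (pGpp strain) and -2.19 ((p)ppGpp strain). Camera adjusted p was 3.6e-10 and 1.0e-13, and 0.218 and 0.195 with an estimated correlation. No camera call in any comparison held with an estimated correlation.

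Ribosomal protein genes moved down in both strains: 49 of 54 fell in each, also adjusted over the list alone, and 1 rose in the pGpp strain. Examples are rpsJ (-3.10 ± 0.20 and -2.32 ± 0.19), rplW (-2.54 ± 0.14 and -2.01 ± 0.14), rplV (-2.32 ± 0.15 and -1.96 ± 0.15) and rplA (-2.32 ± 0.32 and -1.74 ± 0.31). The list median was -1.73 in the pGpp strain (camera adjusted p = 1.9e-09, and 0.322 with an estimated correlation). Ribosomal genes of the (p)ppGpp strain had -1.46 (camera adjusted p = 6.2e-11, and 0.306 with an estimated correlation). The gene that rose, rplI (0.57 ± 0.23), passed at an adjusted p of 0.0484, which became 0.0843 without pGpp strain 0 min replicate 1, 0.937 without pGpp strain 10 min replicate 1 and 0.212 without pGpp strain 0 min replicate 2. It was also 0.0540 with RLE factors, 0.0618 with rRNA kept, 0.146 in a fit of that strain alone and 0.0645 thinned, chosen after seeing the data. In the list of cell division and peptidoglycan synthesis, 22 of 27 genes fell in the pGpp strain and 20 in the (p)ppGpp strain, and 1 rose in each, adjusted over the list alone as well. The amino acid ligase gene murE was at -3.28 ± 0.15 and -2.23 ± 0.15, the division inhibitor gene minC at -2.17 ± 0.09 and -1.39 ± 0.09, the cell shape gene mreC at -2.06 ± 0.09 in the pGpp strain and mbl at -1.64 ± 0.11 in the (p)ppGpp strain. The division gene ftsZ did not pass (-0.12 ± 0.13, adjusted p 0.413, and 0.07 ± 0.13, adjusted p 0.682), and in the pGpp strain it was at 0.12 with library totals as the only scaling. The list median was -1.78 in the pGpp strain (camera adjusted p = 6.5e-10, and 0.0862 with an estimated correlation). Division genes of the (p)ppGpp strain had -1.10 (camera adjusted p = 2.0e-07, and 0.178 with an estimated correlation). The penicillin-binding protein gene pbpH was higher in both strains (1.10 ± 0.29 and 0.80 ± 0.29), but its adjusted p became 0.0774 without pGpp strain 10 min replicate 1 and 0.0537 without pGpp strain 0 min replicate 2, and 0.0845 without (p)ppGpp strain 0 min replicate 1, 0.178 without (p)ppGpp strain 10 min replicate 1 and 0.163 without (p)ppGpp strain 0 min replicate 2. For pbpH it was also 0.0526 without (p)ppGpp strain 10 min replicate 2. Of the list 2 genes rose in the pGpp strain without pGpp strain 10 min replicate 2.

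Genes of amino acid synthesis rose, and so did listed uptake genes. All 11 genes of branched-chain amino acid synthesis rose in both strains, with as many adjusted over the list alone, including ilvD (3.11 ± 0.14 in the pGpp strain and 2.75 ± 0.13 in the (p)ppGpp strain), ilvK (2.65 ± 0.13 and 2.20 ± 0.13), ilvB (2.62 ± 0.17 and 2.27 ± 0.16) and leuB (2.58 ± 0.15 and 2.14 ± 0.15). The medians were 2.62 (pGpp strain) and 2.20 ((p)ppGpp strain). Camera adjusted p was 1.8e-10 and 2.0e-13, and 0.218 and 0.195 with an estimated correlation. CodY is a repressor that binds GTP and branched-chain amino acids, and all 14 listed uptake genes under it rose in both strains, adjusted over the list alone too. The permease gene bcaP was at 4.14 ± 0.18 and 3.77 ± 0.18, the dipeptide permease operon's dppA at 3.67 ± 0.27 and 2.85 ± 0.26, and nupP at 2.70 ± 0.15 and 2.37 ± 0.15. This list had medians of 3.26 (pGpp strain) and 2.64 ((p)ppGpp strain). Camera adjusted p was 9.3e-11 and 7.9e-14, and 0.218 and 0.195 with an estimated correlation.

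For threonine, lysine, serine and methionine synthesis, 13 of 16 genes rose and 1 fell in each strain, adjusted over the list alone as well. The methionine synthase gene metE was at 4.64 ± 0.18 and 3.92 ± 0.18, metI at 3.74 ± 0.17 and 2.89 ± 0.16 and the homoserine dehydrogenase gene hom at 2.10 ± 0.16 and 2.02 ± 0.16. The S-adenosylmethionine synthetase gene metK fell (-2.23 ± 0.22 and -1.56 ± 0.21). The list's medians were 1.41 (pGpp strain) and 1.31 ((p)ppGpp strain). Camera adjusted p was 1.6e-07 and 3.1e-10, and 0.218 and 0.195 with an estimated correlation. All 7 genes of the CtsR heat shock regulon, which encode Clp proteases and their regulators, rose in both strains, adjusted over the list alone too. Its repressor gene ctsR was at 1.84 ± 0.19 and 1.24 ± 0.18, radA at 1.79 ± 0.10 and 1.33 ± 0.10, mcsB at 1.69 ± 0.11 and 1.26 ± 0.11, mcsA at 1.84 ± 0.11 in the pGpp strain and clpE at 1.22 ± 0.10 in the (p)ppGpp strain. The medians were 1.69 (pGpp strain) and 1.22 ((p)ppGpp strain). Camera adjusted p was 5.5e-05 and 5.0e-05, and 0.218 and 0.195 with an estimated correlation.

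Over all 4352 genes tested, 1557 were higher and 1528 lower at 10 min than at 0 min in the pGpp strain, and 1192 were higher and 1285 lower in the (p)ppGpp strain. With library totals as the only scaling, the split was 1856 higher and 1157 lower in the pGpp strain (61.6% higher, against 50.5%) and 1596 higher and 880 lower in the (p)ppGpp strain (64.5%, against 48.1%). With it the median of all genes was 0.28 and 0.24 at 10 min and 0.32 and 0.41 at 20 min (pGpp and (p)ppGpp strain), against 0.04 and 0.00 and 0.03 and -0.02 with TMM factors, and changes here are relative to composition-scaled libraries. The make-up of the RNA moved with time beside the ribosomal, nucleotide and amino acid lists. Transfer-messenger RNA (ssrA), which rescues stalled ribosomes, went from 1.53% of counts at 0 min to 4.17% at 10 min and 8.19% at 20 min in the pGpp strain, and from 1.67% to 3.33% and 4.50% in the (p)ppGpp strain. Transfer RNA genes went from 0.317% to 0.115% and 0.0301%, and from 0.330% to 0.148% and 0.0754%. Residual ribosomal RNA differed between the 2 libraries of a group, with 0.582% and 0.175% at 0 min, 3.35% and 0.1004% at 10 min and 5.75% and 2.19% at 20 min in the pGpp strain (replicates 1 and 2), and 0.132% and 0.144%, 0.458% and 0.273%, and 2.23% and 0.789% in the (p)ppGpp strain.

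**Figure D2:**
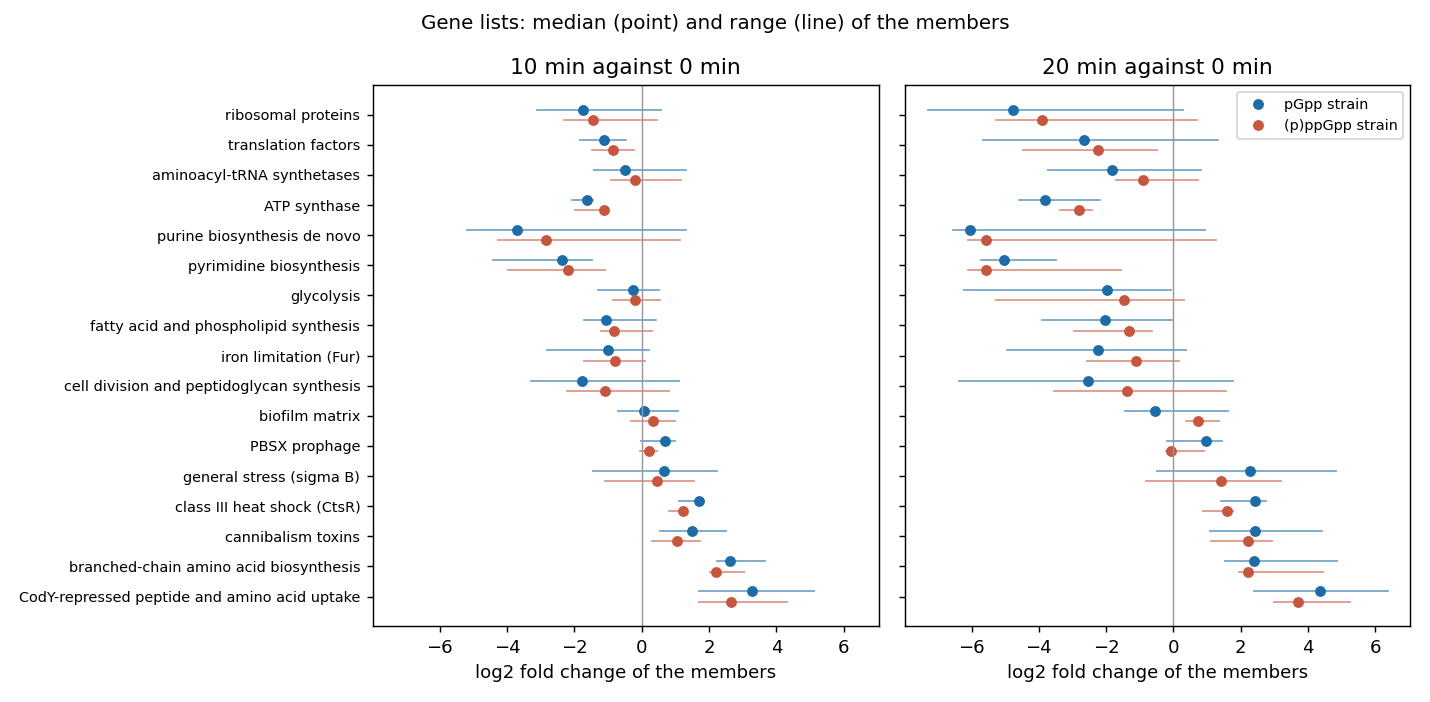
Median log2 fold change against 0 min (point) and range over the tested members (line) for 17 gene lists at 10 and 20 min in both strains. Pyrimidine synthesis has medians of -5.05 and -5.57 at 20 min, and CodY-repressed uptake 4.34 and 3.70.

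By 20 min ribosomal protein genes were among the falls named in the pGpp strain, again with at most 2 genes that share their first 3 letters. These were the short RNA ldlJ (-7.67 ± 0.30), the ribosomal protein genes rpsJ (-7.30 ± 0.25, positions 135364 to 135672), rplJ (-7.11 ± 0.32), rplC (-6.92 ± 0.35) and rpsS (-6.61 ± 0.23), the purine gene purQ (-6.55 ± 0.35), rulS (-6.53 ± 0.17) and the tRNA pseudouridine synthase gene truA (-6.37 ± 0.18). Rises named there were yhzC (8.34 ± 0.51), xylA (7.34 ± 0.23), the extracellular protease gene vpr (6.81 ± 0.52), ycgA (6.80 ± 0.19), yuiA (6.78 ± 0.35), yhxC (6.77 ± 0.15), yxbB (6.76 ± 0.83) and yxbC (6.51 ± 0.67). Falls named in the (p)ppGpp strain were pyaB (-7.06 ± 0.26) and the nucleotide synthesis genes pyrAA (-6.11 ± 0.22), purN (-6.10 ± 0.30), pyrC (-6.06 ± 0.16), purM (-5.96 ± 0.25) and guaC (-5.57 ± 0.18), with the glucose transporter gene ptsG (-5.28 ± 0.27) and rplE (-5.27 ± 0.36). Its named rises were yhzC (6.56 ± 0.47), xylA (6.53 ± 0.22), ycgA (6.32 ± 0.19), yuiA (5.79 ± 0.34), yxbB (5.76 ± 0.80), vpr (5.65 ± 0.50), yxnB (5.57 ± 0.77) and sasA. Adjusted p values of these genes were 8.0e-05 or less in edgeR.

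In each strain 52 of 54 ribosomal protein genes had fallen at 20 min, with the same number adjusted over the list alone. Examples are rplW (-6.75 ± 0.18 in the pGpp strain and -4.53 ± 0.16 in the (p)ppGpp strain), rplV (-6.23 ± 0.18 and -4.71 ± 0.16), rpsQ (-5.80 ± 0.18 and -4.97 ± 0.18) and rplA (-4.67 ± 0.36 and -3.29 ± 0.33). The median was -4.78 in the pGpp strain (camera adjusted p = 1.1e-18, and 0.259 with an estimated correlation). Ribosomal genes of the (p)ppGpp strain had -3.89 (camera adjusted p = 4.7e-26, and 0.233 with an estimated correlation). In the (p)ppGpp strain rplI was higher (0.69 ± 0.23, adjusted p 0.0220), which became 0.0567 without (p)ppGpp strain 0 min replicate 1, 0.0920 without (p)ppGpp strain 20 min replicate 1 and 0.0987 without (p)ppGpp strain 0 min replicate 2. Translation factor genes fell for 16 of 17 in the pGpp strain and for all 17 in the (p)ppGpp strain, adjusted over the list alone as well. The ribosome recycling factor gene frr was at -5.05 ± 0.17 and -3.24 ± 0.15, and the elongation factor gene tufA at -2.02 ± 0.18 and -2.24 ± 0.18. In the pGpp strain lepA was at -2.63 ± 0.11 and fmt at -2.20 ± 0.09, while the release factor gene prfB rose (1.32 ± 0.11). In the (p)ppGpp strain infA was at -4.48 ± 0.26 and mapA at -4.32 ± 0.27. This list had a median of -2.65 in the pGpp strain (camera adjusted p = 2.9e-06, and 0.285 with an estimated correlation). Factor genes of the (p)ppGpp strain had -2.24 (camera adjusted p = 2.1e-07, and 0.235 with an estimated correlation).

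Aminoacyl-tRNA synthetase genes, which charge tRNAs, fell for 22 of 26 in the pGpp strain with 2 rising, and for 17 in the (p)ppGpp strain with 3 rising. The numbers adjusted over the list alone were identical. The alanyl enzyme gene alaS was at -3.26 ± 0.11 and -1.62 ± 0.11, glyQ at -2.93 ± 0.12 and -1.35 ± 0.11, cysS at -2.56 ± 0.10 in the pGpp strain and proS at -1.72 ± 0.14 in the (p)ppGpp strain. Those that rose were metS (0.47 ± 0.09 and 0.38 ± 0.09), thrZ (0.83 ± 0.11 and 0.74 ± 0.11) and, in the (p)ppGpp strain, trpS (0.46 ± 0.09). The list's median was -1.81 in the pGpp strain (camera adjusted p = 6.6e-05, and 0.432 with an estimated correlation). Synthetase genes of the (p)ppGpp strain had -0.90 (camera adjusted p = 0.0137, and 0.606 with an estimated correlation). All 9 ATP synthase genes fell in both strains, adjusted over the list alone too, such as atpA (-3.84 ± 0.24 and -2.86 ± 0.23), atpB (-3.55 ± 0.14 and -2.52 ± 0.14) and atpF (-3.81 ± 0.17 and -2.63 ± 0.16), with atpH at -3.82 ± 0.18 in the pGpp strain and atpI at -2.43 ± 0.14 in the (p)ppGpp strain. That list's median was -3.82 in the pGpp strain (camera adjusted p = 3.2e-05, and 0.330 with an estimated correlation). ATP synthase genes of the (p)ppGpp strain had -2.81 (camera adjusted p = 1.9e-06, and 0.235 with an estimated correlation).

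Purine synthesis kept 13 of 14 genes lower and 1 higher in each strain at 20 min, adjusted over the list alone as well. The genes purE (-5.27 ± 0.14 and -5.52 ± 0.14), purK (-5.59 ± 0.21 and -5.56 ± 0.21) and purM in the pGpp strain (-6.06 ± 0.26) were lower, and purT (0.93 ± 0.13 and 1.26 ± 0.13) was higher. The list's median was -6.06 in the pGpp strain (camera adjusted p = 7.3e-08, and 0.290 with an estimated correlation). Purine genes of the (p)ppGpp strain had -5.58 (camera adjusted p = 5.0e-14, and 0.233 with an estimated correlation). All 13 pyrimidine genes fell in both strains, adjusted over the list alone too. Here pyrR stood at -4.62 ± 0.13 and -4.68 ± 0.13, pyrB at -4.77 ± 0.13 and -5.88 ± 0.13, and pyrC in the pGpp strain at -5.05 ± 0.15, with a list median of -5.05 in the pGpp strain (camera adjusted p = 4.7e-11, and 0.259 with an estimated correlation). Pyrimidine genes of the (p)ppGpp strain had -5.57 (camera adjusted p = 3.7e-21, and 0.233 with an estimated correlation). The 14 CodY-repressed uptake genes all rose again in both strains, and did so adjusted over the list alone. Here appD was at 6.36 ± 0.23 and 5.25 ± 0.22, dppA at 4.77 ± 0.28 and 3.68 ± 0.27, bcaP at 3.98 ± 0.18 and 3.91 ± 0.18 and nupP at 3.52 ± 0.15 and 3.45 ± 0.15. The median of this list was 4.34 in the pGpp strain (camera adjusted p = 2.7e-08, and 0.287 with an estimated correlation). Uptake genes of the (p)ppGpp strain had 3.70 (camera adjusted p = 1.0e-12, and 0.233 with an estimated correlation).

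Glycolysis and lipid synthesis genes mostly fell. Among genes of glycolysis, glucose transport and pyruvate dehydrogenase, 16 of 17 fell in each strain and 1 rose in the (p)ppGpp strain, with no different number adjusted over the list alone. The glucose transporter gene ptsG was at -6.22 ± 0.28 in the pGpp strain and pdhA at -4.85 ± 0.22 and -3.00 ± 0.20, with pfkA at -2.07 ± 0.12 in the pGpp strain and ptsH at -1.98 ± 0.12 in the (p)ppGpp strain. The riser, pgi (0.30 ± 0.09, adjusted p 0.0156), went to 0.0683 without (p)ppGpp strain 0 min replicate 1, 0.0639 without (p)ppGpp strain 20 min replicate 1 and 0.0642 without (p)ppGpp strain 0 min replicate 2. For pgi it was also 0.0792 without (p)ppGpp strain 20 min replicate 2. The list's median was -1.98 in the pGpp strain (camera adjusted p = 0.00167, and 0.478 with an estimated correlation). Glycolysis genes of the (p)ppGpp strain had -1.46 (camera adjusted p = 5.4e-04, and 0.391 with an estimated correlation). Fatty acid and phospholipid synthesis had 15 of 18 genes lower in the pGpp strain and all 18 in the (p)ppGpp strain, adjusted over the list alone as well, among them fabF (-3.91 ± 0.17 and -2.96 ± 0.16), fabD (-3.45 ± 0.14 and -2.36 ± 0.13) and fabHA (-3.16 ± 0.19 and -2.69 ± 0.19). Also lower were cdsA in the pGpp strain (-3.06 ± 0.12) and fabG in the (p)ppGpp strain (-2.27 ± 0.14). This list's median was -2.03 in the pGpp strain (camera adjusted p = 6.6e-05, and 0.276 with an estimated correlation). Lipid genes of the (p)ppGpp strain had -1.33 (camera adjusted p = 1.2e-05, and 0.233 with an estimated correlation). Iron acquisition genes under Fur fell for 24 of 26 in the pGpp strain and for 19 in the (p)ppGpp strain, with equal numbers adjusted over the list alone. These include the siderophore uptake genes fhuB (-4.94 ± 0.16 and -2.57 ± 0.14), fhuG (-3.60 ± 0.13 and -2.10 ± 0.12) and fhuC (-3.29 ± 0.14 and -1.86 ± 0.13) and the bacillibactin synthesis gene dhbA (-3.21 ± 0.34 and -1.19 ± 0.31). The exception fecC (0.36 ± 0.13, adjusted p 0.0207) had an adjusted p of 0.193 without pGpp strain 0 min replicate 2 and 0.151 without pGpp strain 20 min replicate 2. In a fit of that strain alone it was 0.114. The median was -2.25 in the pGpp strain (camera adjusted p = 6.6e-05, and 0.418 with an estimated correlation). Fur genes of the (p)ppGpp strain had -1.13 (camera adjusted p = 0.00898, and 0.509 with an estimated correlation).

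Stress, toxin and antibiotic genes went up. Of 37 general stress genes under sigma B, 35 rose in the pGpp strain and 31 in the (p)ppGpp strain, and 1 fell in each, adjusted over the list alone too. The values were 4.84 ± 0.21 and 3.19 ± 0.19 for gspA and 2.30 ± 0.11 and 1.74 ± 0.11 for clpC, with ywmE at 3.14 ± 0.17 in the pGpp strain and csbX at 1.81 ± 0.12 in the (p)ppGpp strain. The gene of the sigma factor itself, sigB, was at 0.56 ± 0.18 (adjusted p 0.0149) in the pGpp strain, where the adjusted p was 0.0900 without pGpp strain 0 min replicate 1 and 0.103 without pGpp strain 20 min replicate 2, and 0.0595 in a fit of that strain alone. In the (p)ppGpp strain it did not pass (0.31 ± 0.18, adjusted p 0.145), though it did with culture as a block (0.0194), with library totals alone (0.00422) and in a fit of that strain alone (0.00910). The gene that fell was yocK (-0.48 ± 0.14 and -0.82 ± 0.14), with an adjusted p in the pGpp strain of 0.0717 without pGpp strain 20 min replicate 2 and 0.261 with library totals alone. The list's median was 2.27 in the pGpp strain (camera adjusted p = 3.2e-07, and 0.273 with an estimated correlation). Stress genes of the (p)ppGpp strain had 1.42 (camera adjusted p = 3.1e-06, and 0.235 with an estimated correlation). All 12 cannibalism toxin genes rose in both strains, adjusted over the list alone as well, including skfE (2.87 ± 0.25 and 2.78 ± 0.25) and skfA (2.35 ± 0.49 and 1.30 ± 0.48), whose adjusted p in the (p)ppGpp strain (0.0324) became 0.0894 without (p)ppGpp strain 0 min replicate 1, 0.182 without (p)ppGpp strain 20 min replicate 1 and 0.127 without (p)ppGpp strain 0 min replicate 2. Others were sdpA (3.57 ± 0.26) and sdpI (2.48 ± 0.16) in the pGpp strain and skfF (2.37 ± 0.19) and skfH (2.20 ± 0.21) in the (p)ppGpp strain. The list median was 2.41 in the pGpp strain (camera adjusted p = 0.00482, and 0.432 with an estimated correlation). Toxin genes of the (p)ppGpp strain had 2.22 (camera adjusted p = 8.7e-04, and 0.334 with an estimated correlation).

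Antibiotic synthesis genes rose for 13 of 21 in the pGpp strain, where 3 fell, and for 16 in the (p)ppGpp strain, with equal numbers adjusted over the list alone. The bacilysin genes bacA (6.31 ± 0.32 and 5.17 ± 0.30) and bacG (5.17 ± 0.22 and 3.65 ± 0.21) and the polyketide gene pksC (2.67 ± 0.11 and 1.94 ± 0.11) were among them. The 3 that fell were the plipastatin genes ppsD (-1.43 ± 0.16) and ppsE (-1.60 ± 0.14) and the subtilosin gene albA (-0.49 ± 0.15), whose adjusted p became 0.0595 without pGpp strain 0 min replicate 2 and 0.114 without pGpp strain 20 min replicate 2, and 0.162 with library totals alone. The list's median was 2.33 in the pGpp strain (camera adjusted p = 0.00465, and 0.553 with an estimated correlation). Antibiotic genes of the (p)ppGpp strain had 2.54 (camera adjusted p = 1.0e-05, and 0.358 with an estimated correlation). In the pGpp strain 24 of 25 genes of the defective prophage PBSX rose, also adjusted over the list alone, with xre at 1.44 ± 0.18, xkdN at 1.38 ± 0.17 and xhlB at 1.26 ± 0.17, while xkdA was at -0.20 ± 0.16 (adjusted p 0.250) and at 0.08 with library totals alone. The median of this list was 0.96 (camera adjusted p = 0.0308, and 0.664 with an estimated correlation), and the camera adjusted p was 0.0749 without pGpp strain 20 min replicate 1. In the (p)ppGpp strain 20 of 22 biofilm matrix genes rose, as they did adjusted over the list alone, with a median of 0.74 (camera adjusted p = 0.00355, and 0.235 with an estimated correlation). Exopolysaccharide genes among them were epsA (1.22 ± 0.17), epsC (0.95 ± 0.09), epsI (0.97 ± 0.10) and epsD (1.03 ± 0.12). In the pGpp strain 11 of these 22 genes fell and 7 rose at 20 min, adjusted over the list alone too, with a median of -0.56. Camera did not call the list there (adjusted p = 0.801, and adjusted p = 0.889 with an estimated correlation), while fry, which does not compare it with other genes, did (adjusted p = 0.00488). Lower there were epsN (-1.16 ± 0.10), epsM (-1.44 ± 0.13) and epsI (-0.73 ± 0.10), and higher were epsA (0.80 ± 0.17) and the matrix repressor gene sinR (1.52 ± 0.10). Among the genes called in opposite directions in the 2 strains were epsI, epsM and epsN.

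At 20 min 1842 genes were higher and 1813 lower than at 0 min in the pGpp strain, and 1529 were higher and 1616 lower in the (p)ppGpp strain, of 4352 tested. With library totals alone the (p)ppGpp strain had 2092 higher and 1116 lower (65.2% higher, against 48.6%). Between 10 and 20 min, 1316 genes rose and 1541 fell in the pGpp strain and 807 rose and 988 fell in the (p)ppGpp strain. The latter split was 1151 higher and 610 lower (65.4%, against 45.0%) with library totals alone, and the number of genes was 1044 without the (p)ppGpp strain 20 min replicate 1 and 1110 without the (p)ppGpp strain 10 min replicate 2. The ssrA and tRNA shares above moved with time in the same libraries.

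How far the strains moved together was asked across genes, which are not independent replicates. The log2 fold changes of the 4352 tested genes correlated with r = 0.938 at 10 min and r = 0.904 at 20 min, and no library was shared by the 2 strains. At 20 min 1382 genes were higher and 1439 lower in both strains, where independent lists of those sizes would share 647 and 673 genes. At 10 min these numbers were 1130 and 1192, against 426 and 451. Genes called in opposite directions numbered 20 at 10 min and 99 at 20 min, against 878 and 1321 for independent lists. Of the 1390 genes that moved the same way in both strains at 20 min and differed between them, 1311 (94.3%) changed more in the pGpp strain, and of 180 such genes at 10 min 179 (99.4%) did.

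**Figure D3:**
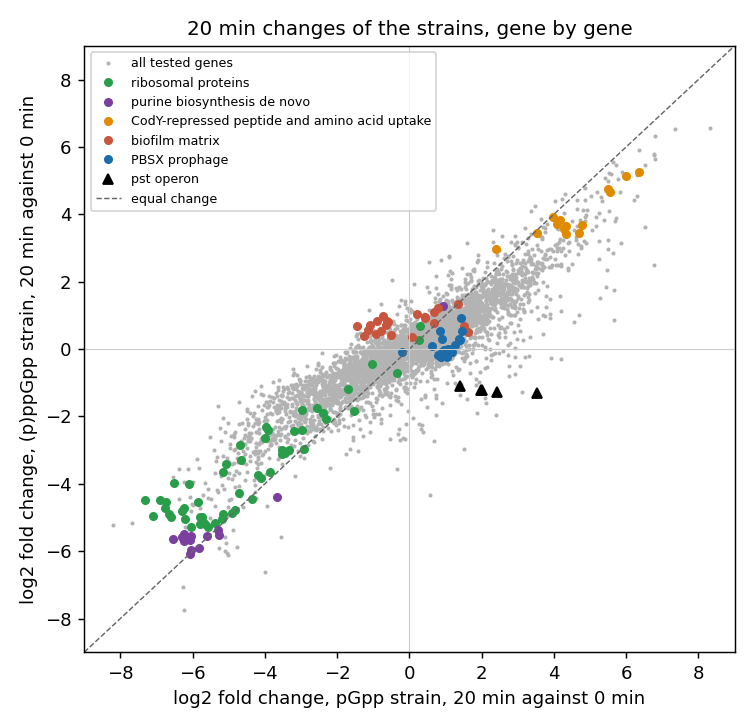
Log2 fold change at 20 min against 0 min in the (p)ppGpp strain (y axis) against the pGpp strain (x axis), 1 point per tested gene (4352), with 5 gene lists and the pst operon marked and a dashed line of equal change. The pst gene pstS lies at 3.54 on the x axis and -1.30 on the y axis.

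The difference of the changes, (p)ppGpp strain minus pGpp strain, was tested at 10 min. Named on the negative side were the 6-phospho-beta-glucosidase gene licH (-3.29 ± 0.19), the guanine deaminase gene guaN (-2.98 ± 0.18), the phosphate-binding protein gene pstS (-2.89 ± 0.41), the protease gene bpr (-2.88 ± 0.43) and yhxC (-2.79 ± 0.18). On the positive side were the purine nucleoside transport gene nupG (1.54 ± 0.32), the xanthine phosphoribosyltransferase gene xpt (1.27 ± 0.23), purC (1.23 ± 0.31), the replicative helicase gene dnaC (1.13 ± 0.21) and fhuB (1.09 ± 0.19). Cell division and peptidoglycan genes had 10 of 27 with a positive difference, and 17 adjusted over the list alone, with mreC at 0.90 ± 0.13 and a median of 0.50 (camera adjusted p = 6.2e-10, and 0.134 with an estimated correlation). For ftsZ the difference was 0.19 ± 0.18 (adjusted p 0.579). Purine synthesis had 3 of 14 positive, purC, purK (1.05 ± 0.24) and purE (0.73 ± 0.17), and 7 adjusted over the list alone, with a median of 0.73 (camera adjusted p = 4.0e-04, and 0.757 with an estimated correlation). The directional test fry did not call this list (adjusted p 0.197). The PBSX list had a median of -0.45 (camera adjusted p = 0.00522, and 0.757 with an estimated correlation), and fry did not call it (adjusted p 0.341). In edgeR 0 of its 25 genes passed, 3 had an unadjusted p under 0.05 and DESeq2 called 0. Its camera adjusted p was 0.151 without pGpp strain 10 min replicate 2 and 0.124 without (p)ppGpp strain 0 min replicate 2.

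In all 119 genes had a positive and 126 a negative difference at 10 min, and 35 and 88 with library totals alone (28.5% positive, against 48.6%). The total of 245 and its even split rested on single libraries: it was 37 (3 positive) without pGpp strain 0 min replicate 1, 52 (11 positive) without pGpp strain 0 min replicate 2 and 956 (573 positive) without pGpp strain 10 min replicate 2. It was 40 (3 positive) without (p)ppGpp strain 0 min replicate 1, 127 (49 positive) without (p)ppGpp strain 10 min replicate 1, 45 (2 positive) without (p)ppGpp strain 0 min replicate 2, 38 (2 positive) without (p)ppGpp strain 10 min replicate 2, and 476 with culture as a block. With the replicate number as a block, chosen after seeing the data, it was 535. Without the pGpp strain 0 min replicate 1 the adjusted p was 0.0829 (nupG), 0.0707 (xpt), 0.143 (purC), 0.0707 (dnaC), 0.0685 (fhuB), 0.143 (purE) and 0.141 (purK), and without replicate 2 0.0831 (nupG), 0.0511 (xpt), 0.114 (purC), 0.0527 (dnaC), 0.0751 (purE) and 0.0827 (purK). Without the pGpp strain 10 min replicate 1 it was 0.0682 (purE). Without the (p)ppGpp strain 0 min replicate 1 it was 0.115 (nupG), 0.0686 (xpt), 0.158 (purC), 0.0745 (dnaC), 0.145 (purE) and 0.133 (purK), and without replicate 2 0.0887 (nupG), 0.0767 (xpt), 0.143 (purC), 0.0705 (dnaC), 0.0756 (fhuB), 0.0995 (purE) and 0.128 (purK). Without the (p)ppGpp strain 10 min replicate 1 it was 0.0715 (purC), and without replicate 2 0.127 (nupG), 0.0878 (xpt), 0.190 (purC), 0.0916 (dnaC), 0.0796 (fhuB), 0.167 (purE) and 0.163 (purK). With library totals alone purE did not pass (0.0857), and with rRNA kept purC did not (0.0571). Positive differences of cell division and peptidoglycan genes numbered 1 without the pGpp strain 0 min replicate 1, the (p)ppGpp strain 0 min replicate 1 or 2 or the (p)ppGpp strain 10 min replicate 2, 2 without the pGpp strain 0 min replicate 2 and 17 without the pGpp strain 10 min replicate 2. Those of purine genes numbered 11 without the pGpp strain 10 min replicate 2, with none left without the pGpp strain 0 min replicate 1 or 2, the (p)ppGpp strain 0 min replicate 1 or 2 or the (p)ppGpp strain 10 min replicate 2. Adjusted over the list alone they numbered 3 without the pGpp strain 0 min replicate 1 or the (p)ppGpp strain 0 min replicate 1, 4 without the pGpp strain 0 min replicate 2 or the (p)ppGpp strain 0 min replicate 2 and 12 without the pGpp strain 10 min replicate 2, with none left without the (p)ppGpp strain 10 min replicate 2.

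At 20 min the heptaprenyl diphosphate synthase gene hepT (3.14 ± 0.19), pbtP (3.12 ± 0.21), the flagellar export genes flhB (3.02 ± 0.32) and flhA (3.02 ± 0.23) and the chemotaxis gene cheB (2.96 ± 0.21) were named for positive differences, (p)ppGpp strain minus pGpp strain. For negative ones these were pstS (-4.85 ± 0.41), licH (-4.49 ± 0.19), yhxC (-4.29 ± 0.18), guaN (-3.90 ± 0.18) and bpr (-3.76 ± 0.43). Ribosomal protein genes differed for 24 of 54, all positive, so that they fell less in the (p)ppGpp strain, with the same number adjusted over the list alone. These include rpsJ (2.81 ± 0.27), rpsL (2.54 ± 0.24), rplW (2.22 ± 0.20) and rplA (1.39 ± 0.43), whose adjusted p of 0.0244 became 0.0567 without pGpp strain 0 min replicate 1, 0.0900 without pGpp strain 20 min replicate 1 and 0.0543 without pGpp strain 0 min replicate 2. For rplA it was also 0.0699 without (p)ppGpp strain 0 min replicate 1, 0.0605 without (p)ppGpp strain 0 min replicate 2 and 0.0764 without (p)ppGpp strain 20 min replicate 2. The list median was 0.58 (camera adjusted p = 1.5e-04, and 0.777 with an estimated correlation). For aminoacyl-tRNA synthetases 19 of 26 differences were positive and 1 negative, asnS (-0.67 ± 0.16), and 20 and 1 adjusted over the list alone. Examples are cysS (1.68 ± 0.13), alaS (1.63 ± 0.15) and glyQ (1.58 ± 0.15), and the median was 0.94 (camera adjusted p = 1.5e-05, and 0.679 with an estimated correlation).

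Cell division and peptidoglycan genes had 19 of 27 positive differences at 20 min, as many adjusted over the list alone, with mreC at 2.25 ± 0.13, mreB at 1.89 ± 0.13, murC at 2.51 ± 0.19 and ftsZ at 0.26 ± 0.18 (adjusted p 0.272). The median was 1.03 (camera adjusted p = 2.0e-07, and 0.276 with an estimated correlation). Iron acquisition genes under Fur showed 20 of 26 positive, and 23 positive with 1 negative adjusted over the list alone. For fhuB the difference was 2.37 ± 0.20, for dhbA 2.03 ± 0.44, for efeM 1.70 ± 0.20 and for fhuG 1.51 ± 0.17, and the median was 1.45 (camera adjusted p = 1.5e-05, and 0.679 with an estimated correlation). In the motility list 21 of 45 differences were positive, such as cheD (2.39 ± 0.17) and fliP (2.33 ± 0.17), and 6 were negative, among them that of the flagellin gene hag (-0.96 ± 0.29), with equal numbers adjusted over the list alone. The adjusted p of hag, 0.0198, became 0.0729 without pGpp strain 20 min replicate 1, 0.0823 without pGpp strain 0 min replicate 2 and 0.0619 without (p)ppGpp strain 0 min replicate 1. For hag it was also 0.0518 without (p)ppGpp strain 0 min replicate 2 and 0.0771 without (p)ppGpp strain 20 min replicate 2. This list's median was 0.26 (camera adjusted p = 1.5e-04, and 0.679 with an estimated correlation). Biofilm matrix genes had 14 of 22 positive and 2 negative, adjusted over the list alone as well. Positive were epsN (1.72 ± 0.14), epsI (1.71 ± 0.14) and epsM (2.12 ± 0.18), with epsA at 0.42 ± 0.24 (adjusted p 0.178). Negative were sinR (-0.85 ± 0.14), the gene of the matrix repressor, and the surface layer gene bslA (-1.11 ± 0.38), whose adjusted p of 0.0352 became 0.0548 without pGpp strain 0 min replicate 1, 0.148 without pGpp strain 20 min replicate 1 and 0.108 without pGpp strain 0 min replicate 2. For bslA it was also 0.121 without (p)ppGpp strain 0 min replicate 1 and 0.120 without (p)ppGpp strain 20 min replicate 2. Thinned, it was 0.0512. The biofilm median was 1.13 (camera adjusted p = 3.0e-05, and 0.369 with an estimated correlation).

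General stress genes went the other way: 25 of 37 differences were negative and 1 positive, and 26 and 1 adjusted over the list alone. The differences were -1.64 ± 0.25 for gspA, -1.07 ± 0.15 for ctc and -0.87 ± 0.17 for ycdF, with -0.25 ± 0.26 (adjusted p 0.455) for sigB. The negative ones numbered 15 without the pGpp strain 0 min replicate 1, the pGpp strain 20 min replicate 1 or the (p)ppGpp strain 0 min replicate 2 and 16 without the (p)ppGpp strain 20 min replicate 2. The positive one, csbX (0.51 ± 0.17, adjusted p 0.0301), became 0.0653 without pGpp strain 20 min replicate 1, 0.0889 without pGpp strain 0 min replicate 2 and 0.0523 without pGpp strain 20 min replicate 2. For csbX it was also 0.110 without (p)ppGpp strain 0 min replicate 1 and 0.107 without (p)ppGpp strain 20 min replicate 1. The list median was -0.82 (camera adjusted p = 1.5e-04, and 0.679 with an estimated correlation). PBSX prophage genes had 19 of 25 negative, and 20 adjusted over the list alone, with xhlB at -1.15 ± 0.24, xkdN at -1.08 ± 0.23, xkdG at -1.14 ± 0.25 and xkdA at 0.11 ± 0.22 (adjusted p 0.710). The median was -1.08 (camera adjusted p = 1.5e-04, and 0.777 with an estimated correlation). Altogether 1123 genes had a positive and 899 a negative difference at 20 min, and 1235 and 631 with library totals alone (66.2% positive, against 55.5%).

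Before induction edgeR called 8 genes between the strains. The 5 genes of the pst operon, which encode the high-affinity phosphate transporter (positions 2577210 to 2581617, minus strand), were higher in the (p)ppGpp strain. The differences (log2) were 6.96 ± 0.34 for pstS, 6.20 ± 0.18 for pstC, 7.76 ± 0.26 for pstA, 7.70 ± 0.19 for pstBA and 6.82 ± 0.16 for pstBB, with adjusted p of 1.5e-06 or less in edgeR. Levels of pstC were 3.91 and 3.48 CPM in the 2 pGpp strain libraries at 0 min against 269 and 276 CPM in the 2 (p)ppGpp strain libraries. The fructosamine permease genes frlM (1.29 ± 0.20, adjusted p 0.0304) and frlN (1.29 ± 0.18, adjusted p 0.0191) were higher too. Their calls did not hold when a library was left out, where the adjusted p of frlM was 0.291 without pGpp strain 0 min replicate 1, 0.503 without pGpp strain 0 min replicate 2 and 0.362 without (p)ppGpp strain 0 min replicate 1. For frlM it was also 0.119 without (p)ppGpp strain 0 min replicate 2. That of frlN was 0.189 without pGpp strain 0 min replicate 1, 0.399 without pGpp strain 0 min replicate 2 and 0.258 without (p)ppGpp strain 0 min replicate 1. For frlN it was also 0.0935 without (p)ppGpp strain 0 min replicate 2. The deleted nahA (yvcI) was lower (-7.47 ± 0.38). With the replicate number as a block 14 genes passed, and 13 did in DESeq2. During induction pstS went up in the pGpp strain (3.54 ± 0.32 at 20 min) and down in the (p)ppGpp strain (-1.30 ± 0.26).

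**Figure D4:**
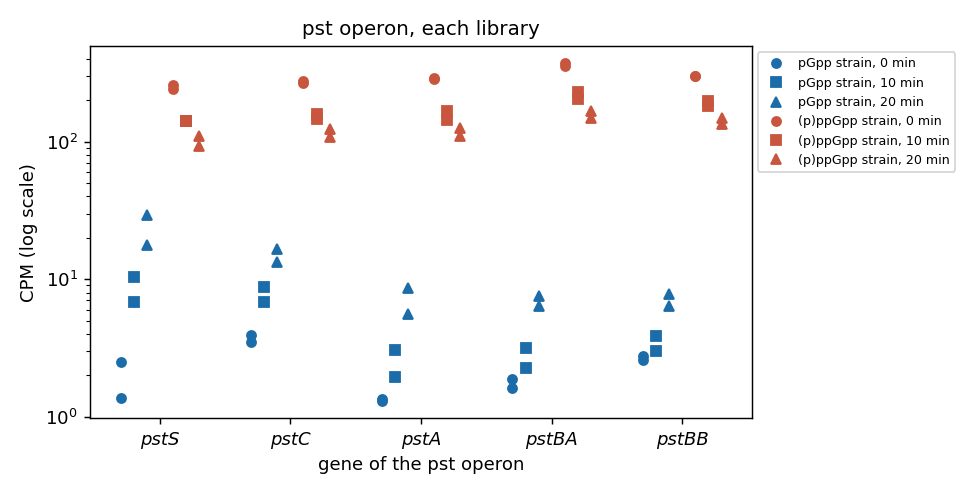
CPM of the 5 pst operon genes in each of the 12 libraries by strain and minutes after induction. The pGpp strain libraries run from 1.29 (pstA) to 29.3 (pstS) CPM and the (p)ppGpp strain libraries from 93.8 (pstS) to 376 (pstBA) CPM.

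Of the lists, the PBSX prophage had a median difference of 0.50 between the strains at 0 min (camera adjusted p = 6.0e-14, and 0.878 with an estimated correlation). CodY-repressed uptake had 0.39 (camera adjusted p = 7.1e-06, and 0.878 with an estimated correlation). Branched-chain amino acid synthesis had 0.30 (camera adjusted p = 4.1e-04, and 0.878 with an estimated correlation). No single gene of these lists passed in edgeR, over all genes or adjusted over the list alone, or in DESeq2 over all genes (0 in each). In edgeR 17, 4 and 2 had an unadjusted p under 0.05. The members with the smallest p were xkdC (0.78 ± 0.20), xkdS (0.57 ± 0.16) and xkdP (0.53 ± 0.16) of PBSX and nupP (0.46 ± 0.15), bcaP (0.47 ± 0.16) and dppC (0.58 ± 0.25) of the CodY list. In the branched-chain list they were leuD (0.44 ± 0.15), leuB (0.38 ± 0.14) and leuA (0.30 ± 0.14). Adjusted p was 0.825 for xkdC and 0.999 for the others. The directional test fry called none of these lists, with adjusted p of 0.387, 0.391 and 0.387. In all 9 of 41 lists passed camera, and 3 without the pGpp strain 0 min replicate 1, 5 without the (p)ppGpp strain 0 min replicate 1 and 4 without the (p)ppGpp strain 0 min replicate 2. The adjusted p of the branched-chain list was 0.0713 without (p)ppGpp strain 0 min replicate 1.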

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

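The tests of the sasA rises and levels and of genes called in opposite directions, the thinning, the number block of the sasA and xylB levels, and the condition that the difference of correlations exceed its spread were chosen only after the results were seen.

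One pattern is the pst operon, higher by 6.20 to 7.76 (log2) in the (p)ppGpp strain before induction. A phosphate response of the whole PhoP regulon is argued against by the 16 PhoP-activated genes outside the operon, whose median difference was -0.034 (range -0.11 to 0.53), each with an edgeR adjusted p of 0.999. A single deviating or mixed-up library is argued against too, since the lower (p)ppGpp strain library lay 6.78 (log2) above the higher pGpp strain library in the median pst gene, and nahA was lost in both. A change particular to this strain, such as the nahA deletion or another difference in its construction, stays open, inseparable from the strain and untested.

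A further pattern is that 94.3% of the genes that moved the same way at 20 min and differed between strains changed more in the pGpp strain. Lower depth is argued against, since 1897 genes were still called for the difference after thinning, against 2022, and composition scaling likewise, since the share was 93.1% with library totals alone. A higher sasA transcript level in the pGpp strain stays open at 20 min: the difference of its rises was -0.27 ± 0.34 (adjusted p 0.549), which decides neither way, and its level differed by -0.53 ± 0.24 (unadjusted p 0.0482 in edgeR, adjusted p 0.0755, and adjusted p 0.0388 with the replicate number as a block), and xylA (-1.02 ± 0.17, adjusted p 6.0e-04), amyE (-0.52 ± 0.10, adjusted p 0.00129) and xylB (-0.40 ± 0.11, adjusted p 0.0112) were lower in the (p)ppGpp strain. At 10 min 179 of 180 such genes changed more in the pGpp strain. By the test's condition the difference of the sasA rises (0.0348 ± 0.34, adjusted p 0.963) argued against a larger rise in the pGpp strain. Its standard error leaves a small one open. The levels of sasA (-0.23 ± 0.24, adjusted p 0.529) and xylA (-0.34 ± 0.17, adjusted p 0.201) decide neither way. Nor does xylB (-0.37 ± 0.11, adjusted p 0.0532, 0.0214 with the number block), and amyE hardly differed (-0.06 ± 0.10, adjusted p 0.739). The alarmone itself, the explanation named by the design, stays open and untested, since strain and inducer level cannot be separated. So does a slower course in the (p)ppGpp strain.

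In the last pattern the 20 min profiles differed, with 99 genes called in opposite directions, 57 rising and 42 falling in the pGpp strain. With a much slower course, (p)ppGpp strain changes at 20 min should correlate better with 10 min than with 20 min of the pGpp strain. A mildly slower one need not show this. The difference of correlations was below 0 in all 4 pairings of cultures (mean -0.0314, lowest -0.0614, highest -0.0033, SD 0.0284). By the condition written beforehand this argued against a slower course. The test cannot weigh a mildly slower one, and the condition on the spread, applied once the values were known, leaves the question open. Of the 99 genes 16 (16.2%) were called in the pGpp strain at 10 min in the direction of the (p)ppGpp strain at 20 min, 40 in the direction of the pGpp strain at 20 min and 43 not at all, which decides neither way. A difference between the alarmones in which genes respond was not tested separately from the strains and stays open.

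The remaining results are given as values. The test of the difference of changes between strains passed for 245 genes at 10 min (37 without the pGpp strain 0 min replicate 1, 956 without the pGpp strain 10 min replicate 2, and as listed in the report for the others) and 2022 at 20 min. Differences at 10 min, (p)ppGpp strain minus pGpp strain (log2), were as follows. Genes dnaC (1.13), fhuB (1.09), mbl (0.85), minC (0.77), mreB (0.80), mreC (0.90) and murE (1.05) were positive. Genes nupG (1.54), purC (1.23), purE (0.73), purK (1.05), xpt (1.27), yrrM (1.09) and yrrN (0.99) were positive. Genes bpr (-2.88), guaN (-2.98), licH (-3.29), mcsA (-0.63), metI (-0.86), pstS (-2.89) and yhxC (-2.79) were negative. Values of nupG, xpt, purC, purE, purK, dnaC and fhuB without single libraries are in the report. Without the pGpp strain 0 min replicate 1 the adjusted p of other genes was 0.0627 (mreB), 0.0555 (minC), 0.0851 (yrrM), 0.0707 (yrrN), 0.143 (metI), 0.157 (mcsA), 0.0809 (murE) and 0.0764 (mbl), and without replicate 2 0.0505 (minC), 0.0505 (yrrM), 0.0511 (yrrN), 0.176 (metI), 0.122 (mcsA), 0.0527 (murE) and 0.0505 (mbl). Without the pGpp strain 10 min replicate 1 it was 0.0599 (metI) and 0.0557 (mcsA). Without the (p)ppGpp strain 0 min replicate 1 it was 0.0523 (mreB), 0.0622 (minC), 0.0748 (yrrM), 0.0629 (yrrN), 0.188 (metI), 0.144 (mcsA), 0.0656 (murE) and 0.0629 (mbl), and without replicate 2 0.0656 (mreB), 0.0616 (minC), 0.0926 (yrrM), 0.0835 (yrrN), 0.131 (metI), 0.162 (mcsA), 0.0926 (murE) and 0.0895 (mbl). Without the (p)ppGpp strain 10 min replicate 1 it was 0.0864 (metI) and 0.111 (mcsA), and without replicate 2 0.0542 (mreB), 0.0710 (minC), 0.102 (yrrM), 0.0756 (yrrN), 0.203 (metI), 0.142 (mcsA), 0.1004 (murE) and 0.0878 (mbl). It was also 0.0512 (metI) with RLE factors, 0.0854 (metI) and 0.154 (mcsA) with library totals alone, 0.0704 (metI) with rRNA kept and 0.0578 (metI) thinned.

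Camera called 13 lists for the difference at each time. At 10 min their median differences were 0.29 for ribosomal proteins, 0.30 for translation factors, 0.38 for ribosome assembly GTPases and maturation, 0.49 for ATP synthase, 0.73 for purine biosynthesis de novo and -0.43 for branched-chain amino acid biosynthesis. Further ones at 10 min were -0.63 for CodY-repressed peptide and amino acid uptake, -0.43 for class III heat shock (CtsR), 0.25 for fatty acid and phospholipid synthesis, 0.25 for DNA replication, 0.50 for cell division and peptidoglycan synthesis, -0.45 for PBSX prophage and 0.46 for iron limitation (Fur). At 20 min they were 0.58 for ribosomal proteins, 0.74 for translation factors, 0.94 for aminoacyl-tRNA synthetases, 1.00 for ribosome assembly GTPases and maturation, 1.20 for RNA polymerase core and sigma A and -0.82 for general stress (sigma B). Further ones at 20 min were -0.66 for class III heat shock (CtsR), 0.26 for motility and chemotaxis (sigma D and fla/che), 1.13 for biofilm matrix, 0.53 for DNA replication, 1.03 for cell division and peptidoglycan synthesis, -1.08 for PBSX prophage and 1.45 for iron limitation (Fur). The estimated correlation ended each of these calls, with adjusted p of 0.134 to 0.757 at 10 min and 0.276 to 0.777 at 20 min. With fry 4 of the 13 passed at 10 min and all 13 at 20 min.

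Named genes with a difference at 20 min follow. Genes alaS (1.63), atpA (0.98), atpB (1.04), atpF (1.18), atpH (1.01), cdsA (1.63) and cheB (2.96) were positive. Genes cheD (2.39), csbX (0.51), cshA (0.68), cysS (1.68), der (1.32), dhbA (2.03) and dnaA (1.21) were positive. Genes dnaC (2.01), efeM (1.70), epsC (0.52), epsD (0.82), epsI (1.71), epsM (2.12) and epsN (1.72) were positive. Genes era (0.79), fabD (1.09), fabF (0.95), fabG (0.96), fhuB (2.37), fhuC (1.44) and fhuG (1.51) were positive. Genes flhA (3.02), flhB (3.02), fliP (2.33), fmt (1.12), frr (1.80), glyQ (1.58) and hepT (3.14) were positive. Genes kinC (0.47), ldlJ (2.52), lepA (1.502), ligA (1.86), mreB (1.89), mreC (2.25) and murC (2.51) were positive. Genes nusA (1.88), nusB (0.41), pbtP (3.12), pdhA (1.85), pfkA (0.61), pgi (0.36) and polC (1.49) were positive. Genes ppsD (1.71), ppsE (1.37), proS (2.02), ptsG (0.95), rgpH (1.42), rplA (1.39) and rplC (2.43) were positive. Genes rplJ (2.16), rplV (1.52), rplW (2.22), rpoZ (1.94), rpsJ (2.81), rpsL (2.54) and rpsQ (0.83) were positive. Genes rpsS (1.62), rulS (2.74), skfH (1.12), ssbA (1.29), truA (1.92) and yqeI (1.71) were positive. Genes amyE (-0.46), appD (-1.11), asnS (-0.67), bacA (-1.14), bacG (-1.53), bpr (-3.76) and bslA (-1.11) were negative. Genes clpC (-0.56), ctc (-1.07), dppA (-1.09), gspA (-1.64), guaC (-2.01), guaN (-3.90) and hag (-0.96) were negative. Genes licH (-4.49), pksC (-0.74), prfB (-2.41), pstS (-4.85), pyrAA (-1.08), pyrB (-1.10) and pyrC (-1.01) were negative. Genes sdpA (-1.33), sdpI (-1.04), sinR (-0.85), spo0B (-0.69), xhlB (-1.15), xkdG (-1.14) and xkdN (-1.08) were negative. Genes xylA (-0.82), ycdF (-0.87), yhxC (-4.29), yhzC (-1.78) and ywmE (-1.11) were negative. Values of rplA, hag, csbX and bslA without single libraries are in the report. Without the pGpp strain 0 min replicate 1 the adjusted p of other genes was 0.105 (xylA), 0.0729 (ptsG), 0.0651 (atpA), 0.0803 (bacA), 0.0525 (pfkA), 0.0815 (amyE), 0.120 (kinC) and 0.103 (pgi), and without replicate 2 0.0749 (yhzC), 0.0697 (ptsG), 0.126 (nusB), 0.0940 (dppA), 0.0514 (clpC), 0.0590 (bacA) and 0.125 (pgi). Without the pGpp strain 20 min replicate 1 it was 0.0737 (yhzC), 0.0849 (xylA), 0.108 (ptsG), 0.0755 (nusB), 0.0845 (atpA), 0.0923 (dppA), 0.103 (bacA), 0.0674 (kinC) and 0.104 (pgi), and without replicate 2 0.0664 (nusB), 0.0763 (kinC) and 0.0661 (pgi). Without the (p)ppGpp strain 0 min replicate 1 it was 0.0589 (yhzC), 0.0721 (ptsG), 0.104 (nusB), 0.0651 (atpA), 0.0971 (dppA), 0.0772 (bacA), 0.0780 (kinC) and 0.127 (pgi), and without replicate 2 0.0971 (xylA), 0.0883 (ptsG), 0.0898 (nusB), 0.0573 (atpA), 0.0537 (bacA), 0.0597 (pfkA), 0.111 (amyE), 0.104 (kinC) and 0.122 (pgi). Without the (p)ppGpp strain 20 min replicate 1 it was 0.0842 (nusB), 0.0707 (amyE), 0.0716 (kinC) and 0.107 (pgi), and without replicate 2 0.0703 (yhzC), 0.0738 (xylA), 0.0973 (ptsG), 0.106 (nusB), 0.0636 (atpA), 0.0879 (dppA), 0.0925 (bacA), 0.0584 (amyE), 0.0926 (kinC) and 0.131 (pgi). It was also 0.0644 (xylA), 0.0714 (clpC), 0.0687 (spo0B) and 0.201 (amyE) with library totals alone, 0.0532 (nusB) and 0.0525 (pgi) with rRNA kept and 0.0522 (nusB), 0.0625 (kinC) and 0.0757 (pgi) thinned. From 10 to 20 min 2857 genes changed in the pGpp strain and 1795 in the (p)ppGpp strain. The latter was 1044 without the (p)ppGpp strain 20 min replicate 1 and 1110 without the (p)ppGpp strain 10 min replicate 2. Residual rRNA, outside the tests, made up 3.97% of counts (5.75% and 2.19% in replicates 1 and 2) in the pGpp strain at 20 min and 0.366% (0.458% and 0.273%) and 1.51% (2.23% and 0.789%) in the (p)ppGpp strain at 10 and 20 min, where every library lay above those of the same strain at 0 min.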

How the results depend on the processing

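The alternatives chosen after seeing the data were thinning and, for the differences at 10 and 20 min, the replicate number as a block. For named genes 5590 of the alternative values kept direction and side of the threshold, 220 kept the direction and no longer passed, 5 newly passed and 9 changed sign. List tests held 638 times, newly passed 1 time and no longer passed 75 times, 66 of them with an estimated correlation. Counts of genes stayed within 1.5 times in 102 cases and moved further in 22, and counts of lists in 62 and 16.

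A change of at least 2-fold left 1667 and 1048 genes at 10 min (pGpp and (p)ppGpp strain), 1858 at 20 min in the (p)ppGpp strain, 1398 and 583 between 10 and 20 min and 90 and 1179 for the differences at 10 and 20 min, since it adds a condition. For the difference at 10 min library totals gave 123, DESeq2 445 and the culture as a replicate block 476, and between strains at 0 min the replicate number as a block gave 14 and DESeq2 13. That number as a block gave 535 and 2347 for the differences at 10 and 20 min and changed the call of no named gene there. The pairing by culture moved no other count by over 1.5 times and changed 1 other call, that of sigB in the (p)ppGpp strain. With an estimated correlation 0 lists passed camera in each of the 7 comparisons, and with fry, which does not compare a list with other genes, 33 and 40 lists passed in the pGpp strain at 10 and 20 min (camera 19 and 24) and 33 in the (p)ppGpp strain at 10 min (21). For the differences at 10 and 20 min fry called 6 and 24 (camera 13 and 13) and for the strains at 0 min 0 (9). The agreement across genes was 0.924 and 0.893 by Spearman, 0.927 and 0.898 without a low-count filter and 0.973 and 0.932 for genes of average log2 CPM of at least 5. The cause of these differences was not tested beyond what each setting changes by construction.

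Signs of log2 changes differed for ftsZ in the pGpp strain at 10 min (0.12 with library totals), xkdA in the pGpp strain at 20 min (0.0783 with library totals), and era in the (p)ppGpp strain at 20 min (0.31 with library totals). The difference at 10 min of xkdA changed sign too (-0.18 without the pGpp strain 10 min replicate 1, but 0.25 without its replicate 2, -0.01 without the pGpp strain 0 min replicate 2, -0.05 without the (p)ppGpp strain 0 min replicate 1, -0.12 without the (p)ppGpp strain 10 min replicate 2 and -0.0835 thinned), as did its difference at 20 min (-0.0105 thinned). None of the main values had passed the test, era did with library totals (adjusted p 0.0410), and the cause was not tested.

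Leaving out each library in turn gave 2684 to 3161 genes (pGpp strain, 10 min), 3431 to 3516 (20 min), 1890 to 2141 and 2797 to 2872 ((p)ppGpp strain), 2391 to 2846 and 1044 to 1344 (20 against 10 min), 37 to 956 and 1555 to 1964 (differences at 10 and 20 min) and 6 in each case between strains at 0 min, where the pst genes and nahA remained. The extremes of the unstable ones were 1044 without the (p)ppGpp strain 20 min replicate 1, 37 without the pGpp strain 0 min replicate 1 and 956 without the pGpp strain 10 min replicate 2. Lists numbered 18 to 20, 23 to 26, 20 in each case, 25 to 27, 9 to 18, 13 to 16 and 3 to 9 (3 without the pGpp strain 0 min replicate 1), and the agreement was 0.919 to 0.929 and 0.897 to 0.903. A group left with 1 library is assumed to vary like the others. Thinned to 18.2 M fragments, 1897 genes differed between strains at 20 min.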

Other observations

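No test in this part was chosen after the results were seen. The lists below were fixed before the data were examined and picked for description afterwards. Ribosome assembly genes fell for 13 of 14 in the pGpp strain at 20 min and for 12 in the (p)ppGpp strain, with 1 rising in each, and as many adjusted over the list alone. The values were -2.98 ± 0.10 and -1.56 ± 0.10 for rgpH, -3.07 ± 0.13 for yqeI and -2.98 ± 0.13 for der in the pGpp strain, and -1.62 ± 0.10 for the helicase gene cshA and -1.33 ± 0.09 for obgE in the (p)ppGpp strain. The GTPase gene era fell in the pGpp strain (-0.91 ± 0.09), and in the (p)ppGpp strain it was at -0.12 ± 0.09 (edgeR adjusted p 0.254) and at 0.31 with library totals alone. The GTPase gene engB rose (1.19 ± 0.12 and 1.08 ± 0.12). For this list the median was -2.01 in the pGpp strain (camera adjusted p = 1.9e-04, and 0.220 with an estimated correlation). Assembly genes of the (p)ppGpp strain had -1.14 (camera adjusted p = 0.00567, and 0.233 with an estimated correlation). RNA polymerase and its factors fell for 10 of 11 genes in the pGpp strain and for 8 in the (p)ppGpp strain, and 10 and 9 adjusted over the list alone. The alpha subunit gene rpoA was at -3.97 ± 0.27 and -3.70 ± 0.26, nusA at -4.38 ± 0.15 and -2.49 ± 0.14, nusB at -2.71 ± 0.11 and -2.30 ± 0.10 and rpoZ at -3.26 ± 0.14 in the pGpp strain. This list's median was -2.71 in the pGpp strain (camera adjusted p = 0.00146, and 0.220 with an estimated correlation). Polymerase genes of the (p)ppGpp strain had -1.41 (camera adjusted p = 0.00547, and 0.233 with an estimated correlation).

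DNA replication genes fell for 15 of 21 in the pGpp strain and for 17 in the (p)ppGpp strain at 20 min, and as many adjusted over the list alone, with holB rising (0.99 ± 0.09 and 0.88 ± 0.09). Single-strand binding protein gene ssbA was at -4.98 ± 0.21 and -3.69 ± 0.20, dnaC at -3.93 ± 0.17 and -1.93 ± 0.15, the ligase gene ligA at -2.81 ± 0.12 in the pGpp strain and the polymerase gene polC at -2.38 ± 0.17 in the (p)ppGpp strain. The initiator gene dnaA was at -1.82 ± 0.12 and -0.61 ± 0.11, the latter not passing with library totals alone (edgeR adjusted p 0.307). For this list the median was -1.14 in the pGpp strain (camera adjusted p = 0.00146, and 0.276 with an estimated correlation). Replication genes of the (p)ppGpp strain had -0.74 (camera adjusted p = 0.00547, and 0.280 with an estimated correlation). Genes for entry into sporulation rose for 14 of 17 in the pGpp strain and for 12 in the (p)ppGpp strain, also adjusted over the list alone. The master regulator gene spo0A was at 1.98 ± 0.13 and 1.88 ± 0.13, the kinase gene kinA at 2.38 ± 0.15 and 2.12 ± 0.15 and spoIIAB at 4.86 ± 0.31 in the pGpp strain. Those that fell were spo0B (-1.56 ± 0.12 and -2.24 ± 0.12), spoIIE (-1.20 ± 0.24 and -0.78 ± 0.24) and, in the pGpp strain, kinC (-0.65 ± 0.11). In the (p)ppGpp strain the edgeR adjusted p of spoIIE was 0.0593 without (p)ppGpp strain 0 min replicate 2 and 0.102 without (p)ppGpp strain 20 min replicate 2, and 0.115 with library totals alone. The median was 1.98 in the pGpp strain (camera adjusted p = 0.0157, and 0.432 with an estimated correlation). Sporulation genes of the (p)ppGpp strain had 1.48 (camera adjusted p = 0.0137, and 0.391 with an estimated correlation).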
